A study of Homo sapiens with 4 samples.

How the data were processed

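Gene expression was measured in LS174T cells with doxycycline-inducible NICD1 on 4 2-colour arrays, 2 for 12 h and 2 for 24 h of doxycycline at 100 ng/ml, each against RNA taken at 0 h. Per the labels' protocols, total RNA was extracted with RNAbee, and 5 µg per labelling was amplified and coupled to Cy3 or Cy5 with an aminoallyl kit. The first array of each time point had the induced RNA in Cy5 and the 0 h RNA in Cy3, and the second, per the labels a dye flip, had the reverse. The arrays of a dye flip were treated as 1 replicate. The labels name 1 control, the 0 h RNA. They do not state whether both time points used 1 extract of it, or whether the dye flips reused the same RNA, and both were assumed. The simulation of a shared control and the difference of the time points rest on the first. The ratio against it leaves out the control's own spread, and the labels name no cells given doxycycline without the transgene.

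The values are log2 ratios as deposited, 1 column per array and 10368 probes; 0 columns were left unused. The scanner, the background correction and the normalization are not given in the sources used here. The base of the logarithm was settled from the values. On both dye-flip arrays 100% of the values equalled log2 of a ratio of whole numbers plus 1 constant per array (0.445 at 12 h and 0.017 at 24 h), with a relative tolerance of 1e-12 and denominators up to 200000. On these arrays the deposited log2 values therefore carry a global scaling, with no trend of the ratio with signal removed. The medians of the deposited arrays were 0.169 and -0.077 at 12 h and 0.016 and 0.050 at 24 h, so the arrays were not centred on their medians. The direction of the ratios stays unstated and was taken as likely induced over 0 h on all 4 arrays.

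The whole-number ratios gave a lower bound of the signal in both channels of the dye-flip arrays. The mean log2 signal over both channels and both dye-flip arrays, as a percentile among genes, is called the signal percentile. The median ratio changed with signal on 3 arrays. In the dimmest 25% of the genes it was 0.46 and -0.20 at 12 h and 0.02 and 0.17 at 24 h, and in the brightest 25% -0.06 and 0.03 at 12 h and 0.02 and -0.08 at 24 h.

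Probes were named from GEO's platform annotation, which can be old. Of the probes, 9348 had 1 gene symbol, 0 had several and 1020 had none, and 9341 were matched by gene identifier to the RefSeq annotation of assembly GRCh38.p14, which changed 0 symbols. A gene's value on an array was the mean over its probes with a value on every array compared; 396 of the 8790 genes had more than 1 probe. No coordinates are given, because the sources used here name no genome build for the array.

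The 2 arrays of a time point were averaged, which cancels a dye effect, and 0.5 of their difference is given as the technical error. A gene was called when the mean was at least 2-fold (log2 1) and each array at least 1.5-fold in the same direction. The same rule was applied with the dye-flip array negated (the dye part), which serves as a count of technical errors and equals the count under the other reading of the direction. The arrays were not centred for it, so this count includes offsets between the arrays that averaging reduces. The difference of 24 h and 12 h was taken within each dye orientation. With 1 replicate per time point no p-value was computed.

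The calling rule and the list percentiles were tested on simulated data, with errors drawn from the observed dye parts and 200 changed genes. At 12 h (8633 genes) the rule found 0% of genes changed 1.5-fold, 46% of those changed 2-fold, 92% at 3-fold and 96% at 4-fold, with 69 false calls among 8433 unchanged genes. At 24 h (8751 genes) it found 6%, 50%, 96% and 100%, with 42 false calls among 8551. These errors replaced a first error model after its result was seen. In that model each gene kept the size of its own dye part on both arrays, with a random sign on each. The rule then made 307 false calls among the 8433 unchanged genes at 12 h and 152 among the 8551 at 24 h. It found 56% and 62% of genes changed 2-fold. In the data 43 genes were called at 12 h, fewer than the false calls of either model, and 64 at 24 h. The number of false calls therefore depends on how the errors are modelled. The list percentiles were tested with the second model alone. Lists of 20 genes shifted by 0.2 lay in the top 2.5% of random lists in 70 of 100 draws at 12 h and 98 of 100 at 24 h. Unshifted lists lay outside the central 95% in 5 and 7 of 100. These were random draws of genes with independent errors, so a share close to that was set in advance. That share does not cover lists whose members share an error.

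The rule for named genes was fixed before the data were examined. It takes NOTCH1, HES1, ATOH1, MUC2, OLFM4, LGR5, MYC, CDKN1A and KLF4 where measured, and the 10 largest increases and 10 largest decreases among called genes. From each gene list it takes up to 4 called members or otherwise the largest values, and for the difference of the time points the 5 largest each way. In all, 25 gene lists were fixed, with 742 distinct genes, 497 of them measured on all 4 arrays. They cover Notch targets and pathway machinery, intestinal cell types and lineage factors, stem cell and Wnt targets, mitosis, DNA replication, cell cycle inhibitors, ribosomal and mitochondrial genes, stress, secretion, glycolysis, cholesterol synthesis, interferon, NF-kappaB, TGF-beta and MAPK responses, housekeeping, epithelial and mesenchymal genes, and markers of fibroblasts, endothelium and leukocytes. Random lists were matched over 10 bins of the size of the dye part, and for comparing the readings of the direction over 10 bins of recovered signal, with fewer draws. List medians were also set against the median of all genes on each array, and taken with the dye-flip arrays negated (10000 random lists matched on signal), both chosen after the data were seen. For the shared 0 h RNA, 100 simulations drew unchanged cultures against a common control from the pooled values divided by the square root of 2.

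The alternatives planned were stricter and looser calling rules, centring of each array, quantile normalization of the 4 arrays, leaving out the 10% of genes with the largest dye part, counting probes instead of genes, the probe with the smallest dye part, unmatched random lists, correlation over called genes or across dye orientations, and leaving out each array. Leaving out the dimmest 50% of the genes by recovered signal, removing the trend with signal by lowess (span 0.3), matching random lists on signal and counting only probes with a gene symbol were added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used.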

Results

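The experiment followed gene expression after forced activation of the Notch pathway in LS174T cells, a human colon adenocarcinoma line that makes mucins and has features of goblet cells. The line carried a doxycycline-inducible gene for NICD1, the intracellular domain of NOTCH1, which is the active form of the receptor and acts in the nucleus as a transcriptional co-activator. RNA taken 12 h and 24 h after doxycycline at 100 ng/ml was hybridised on 2-colour arrays against RNA taken before doxycycline (0 h). Each time point was measured on 2 arrays, the second with the dyes exchanged (dye flip). The labels do not say whether the dye flips reused the same RNA or whether both time points used the same 0 h extract. Both were assumed, so each time point has 1 replicate, and no difference below has a replicate check. The values are log2 ratios for 10368 probes, of which 9348 carry 1 gene symbol, for 8790 genes. The arrays held values for between 10099 and 10285 probes, and the number of arrays limits the precision.

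The direction of the ratios is not given in the labels, and all signed values below rest on a likely reading: RNA after doxycycline over 0 h RNA on all 4 arrays, the dye-flip arrays having been turned by the authors. The basis is that the induced RNA is channel 2 on all 4 arrays. Under this reading 11 genes were called alike at both times, against 2 with the dye-flip arrays negated. That count does not separate the readings. Had the dye-flip arrays been deposited unturned, dye bias of single probes would also repeat at both times. Pairs of probes for the same gene also went together somewhat better under this reading (r = 0.389 across 114 genes with bright probes, 95% bootstrap interval 0.217 to 0.576, against 0.101, -0.076 to 0.279, with the dye-flip arrays negated), but the intervals overlap. Over probes of any signal it was weaker, at r = 0.105 (-0.022 to 0.238) across 369 genes, against 0.015 (-0.096 to 0.131). These checks were chosen after the data were seen. A further one separated the readings little: 5 of the 25 fixed gene lists at 12 h and 5 at 24 h lay outside the central 95% of random lists matched on recovered signal under this reading, against 5 and 3 with the dye-flip arrays negated. The arrays of 12 h correlated below 0 across probes (r = -0.354), which neither reading excludes, so the direction is not settled, and the counts given below for the dye part are those of the other reading. Opposite signs for all 4 arrays would pass these checks equally well. The targeted gene, NOTCH1, is not among the named probes analysed here, and neither are ATOH1, MUC2 and OLFM4, so induction of the transgene could not be checked.

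The first question was which genes had changed 12 h after induction. PLA2G2A, which encodes a secreted phospholipase A2 of the intestinal epithelium, was 5.13-fold higher (log2 2.36 ± 0.15, the error being 0.5 of the difference between the arrays, here and below). SAT1, the rate-limiting enzyme of polyamine breakdown, was 3.56-fold higher (log2 1.83 ± 0.03), and the trefoil peptide gene TFF1 was 2.71-fold higher (log2 1.44 ± 0.21). DTX1, a known Notch target, was 2.93-fold higher (log2 1.55), but its arrays read 2.10 and 1.01. Its probe was dim, at signal percentile 19.4. Among the genes that fell were GDF15, a stress-induced cytokine of the TGF-beta family, which fell by 1.34 ± 0.03 on the log2 scale, and GCNT3, which encodes a branching enzyme of mucin O-glycans and fell by 1.03 ± 0.11.

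A gene was called when its mean ratio was at least 2-fold and each array showed at least 1.5-fold in the same direction. By this rule 38 of 8633 genes were higher and 5 lower at 12 h. The 10 largest increases were those of SMPX, GRHL2, KIF14, MNS1, SGK1, PLA2G2A, STS, RPA4, CYBRD1 and MAPRE2. PLA2G2A had a bright probe (signal percentile 97.6), whereas the other members of this group had signal percentiles between 0.31 and 33.4. The arrays differed widely for several of these genes: SMPX read 5.03 and 0.69, KIF14 read 4.72 and 0.73, and MNS1 read 4.72 and 0.68. On the Cy5 array KIF14 and MNS1 had identical values, as had CYBRD1 and RPA4 (3.28). The signal percentile comes from the dye-flip arrays and does not show the signal of these genes on the Cy5 array. GRHL2, an epithelial transcription factor, read 2.60 and 3.03, but its signal percentile was 0.31. The 5 decreases were those of TARBP1 (log2 -1.38), GDF15, GPR22 (-1.26), GCNT3 and SERPINI1, which encodes neuroserpin (-1.02). With the dimmest 50% of the genes left out, an alternative chosen after the data were seen, 14 genes were higher and 3 lower.

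Over all genes, the dye part met the rule more often than the change at 12 h. The dye part, which is what remains when the dye-flip array is negated before averaging, met the same rule for 106 genes, against 43 called. Of the 106, 96 were higher and 10 lower. The 106 include an offset between the arrays, with medians over all genes of 0.17 and -0.07, which averaging reduces. They were not counted again after centring. Spearman's rho of the 2 arrays at 12 h was -0.458 across probes. Leaving out the dimmest 50% left 5 genes whose dye part met the rule, against 17 called. With only 1 array the counts moved widely: the Cy5 array alone (without the dye flip) gave 567 higher and 109 lower genes at 2-fold, and the dye-flip array alone gave 39 and 70.

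**Figure D1:**
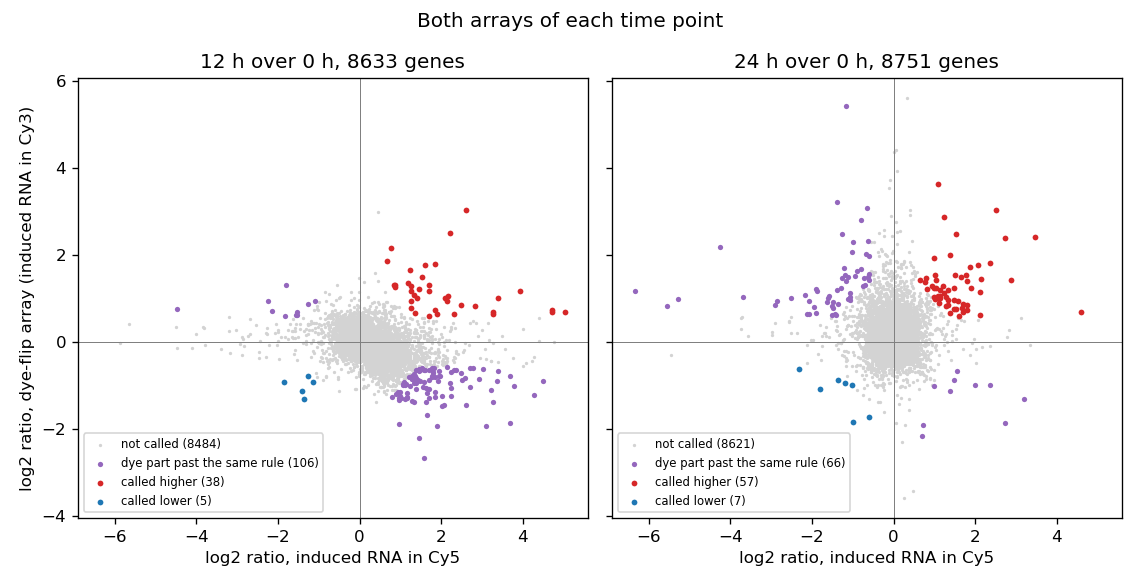
Log2 ratio of each gene on the array with induced RNA in Cy5 (x axis) against the dye-flip array (y axis) at 12 h (8633 genes) and 24 h (8751 genes). Called genes lie in the upper right and lower left (38 and 5 at 12 h, 57 and 7 at 24 h), and genes whose dye part met the same rule lie in the other corners (106 and 66).

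At 24 h, PLA2G2A was 7.70-fold higher (log2 2.95 ± 0.52), SAT1 4.28-fold (log2 2.10 ± 0.27), and SLC2A1, the glucose transporter GLUT1, 4.00-fold (log2 2.0 ± 0.48). SLC3A1, a subunit of the transporter for cystine and dibasic amino acids, was 3.79-fold higher (log2 1.92 ± 0.15). AGR2, a disulfide isomerase needed for mucin folding, fell by 1.43 ± 0.42 on the log2 scale, and SPINK1, a trypsin inhibitor, fell by 1.12 ± 0.25. AKR1B10, an aldo-keto reductase, fell by 1.44 ± 0.36. CDKN2B, which encodes the cyclin-dependent kinase inhibitor p15, was called higher (log2 1.14, arrays 1.04 and 1.24), from a dim probe at signal percentile 2.65.

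The rule called 57 of 8751 genes higher and 7 lower at 24 h. The 10 largest increases were those of PLA2G2A, CWH43 (log2 2.78), AKT2 (2.63), SNAP91 (2.55), IGF2BP2 (2.36), MOBP (2.16), SAT1, SGK1 (2.06), SLC2A1 and SLC3A1. AKT2 read 4.58 and 0.68 on its arrays, at signal percentile 1.0, and SNAP91, MOBP, IGF2BP2 and SGK1 also had signal percentiles of 8.82 or less. CWH43 read 2.52 and 3.04 at signal percentile 45.3. The 7 decreases were those of RHEX (log2 -1.47, arrays -2.32 and -0.63), AKR1B10, AGR2, PBOV1 (-1.16), SPINK1, SERPINI1 (-1.07) and MYL6, a myosin light chain (-1.01, arrays -1.01 and -1.0). PBOV1 had a dim probe, at signal percentile 2.06. With the dimmest 50% left out, 15 genes were higher and 6 lower.

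The dye part at 24 h met the rule for 66 genes, about as many as the 64 called, and for 4 genes with the dimmest 50% left out, against 21 called. Of the 66, 10 were higher and 56 lower, so with the dye-flip array negated most calls at 24 h would be lower instead of higher. The 2 arrays correlated at r = -0.066 across probes, and at r = 0.126 across genes with the dimmest 50% left out. The 12 h arrays still correlated at r = -0.199 across those brighter genes. The dye-flip array alone gave 312 higher and 35 lower genes at 2-fold, and the Cy5 array alone 104 and 120.

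The same genes were then followed across both time points. Of the 8605 genes measured on all 4 arrays, 10 were called higher and 1 lower at both times, and 0 were called in opposite directions. The 10 were PLA2G2A, SAT1, SGK1, SLC2A1, SLC3A1, TFF1, CLU, CNN3, FGFBP1 and NFATC4, and the other was SERPINI1. NFATC4, a transcription factor, read between 1.49 and 1.55 on all 4 arrays. FGFBP1, which encodes a binding protein for fibroblast growth factors, read between 1.20 and 1.36, and the chaperone gene CLU (clusterin) between 1.09 and 1.64. CNN3, which encodes the actin-binding calponin 3, was 2.82-fold higher at 12 h and 3.05-fold at 24 h. SGK1 is the exception in quality: its signal percentile was 0.90 and its errors were 1.38 and 0.82. SERPINI1 was no longer called when each array had to reach 2-fold.

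**Figure D2:**
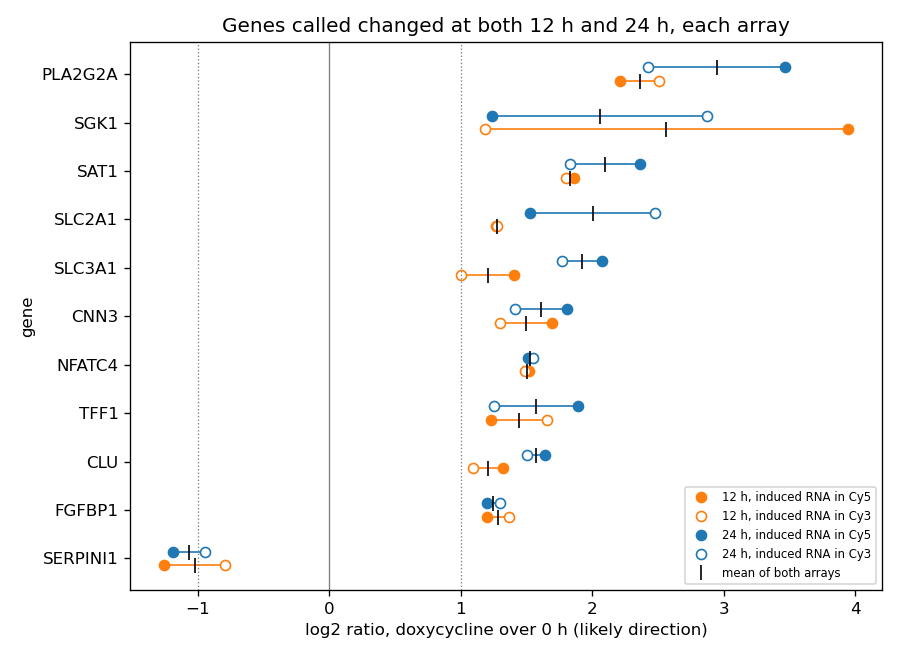
Log2 ratio on each of the 4 arrays for the 11 genes called at both times, with 12 h in orange, 24 h in blue, filled points for induced RNA in Cy5, open points for the dye flip and bars for the means. The dotted lines mark log2 ratios of -1 and 1; all 4 arrays lie on the same side of 0 for each gene, and SGK1 shows the widest gap between arrays.

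Lists of these lengths would share 0.24 higher and 0.0035 lower genes if they were independent and every gene were equally likely to be called. The dye part met the rule in the same direction at both times for 2 genes. The comparisons may share 1 extract of 0 h RNA, however, as was assumed. Simulated unchanged cultures with a common control, with all spread taken as culture spread, gave 14.5 higher and 28.2 lower genes past 2-fold on average at both times, where 15 higher and 1 lower were observed with no demand on single arrays, so part of the overlap may come from that control. Across genes, which are not independent replicates, the changes at 12 h and 24 h correlated at r = 0.232 (rho = 0.255) with a covariance of 0.020. The simulated r of 0.50 and covariance of 0.043 follow from giving cultures and control equal spread, and set no bound on the part due to the control. The correlation depended on dye orientation, and was -0.111 between the dye-flip array at 12 h and the Cy5 array at 24 h. No split of the control was possible.

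The difference between the time points was taken within each dye orientation, where the 0 h RNA cancels if both times used the same extract. The 5 largest increases from 12 h to 24 h were those of LINC00652 (log2 3.24), RALGPS1 (2.65), ADCYAP1 (2.60), IGF2BP2 (2.53) and SNAP91 (2.44). The 5 largest decreases were those of KIF14 (-2.96), GRHL2 (-2.58), CAMK1D (-2.47), NAV3 (-2.01) and PDLIM7 (-2.0). All 10 had dim probes, with signal percentiles of 27.1 or less, and for LINC00652 the orientations read 0.63 and 5.84. In all, 32 of 8605 genes were higher and 19 lower, against 334 whose dye part met the rule, so this comparison was not separated from technical error. The 334 include an offset between the dye orientations, with medians over all genes of -0.13 and 0.11, which averaging reduces. They were not counted again after centring. Of the 334, 4 were higher and 330 lower, so the balance of this comparison also depends on the direction of the dye-flip arrays. Without the dimmest 50%, 0 genes were higher and 2 lower: RHEX (-1.34) and SPINK1 (-1.44), both named after their values were seen. Taking a single dye orientation gave 128 higher and 729 lower genes for the Cy5 arrays and 485 and 24 for the dye-flip arrays.

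The 25 gene lists fixed before the data were examined were described by the median of their measured members and its percentile among 10000 random lists matched on the size of the dye part. Of 13 measured canonical Notch targets, 1 rose at 12 h (DTX1) and 0 at 24 h, when DTX1 read -0.30 and 1.17. The list median was 0.14 at 12 h (0.23 and 0.01 on the arrays, percentile 98.1) and 0.27 at 24 h (0.15 and 0.36, percentile 99.9), with 9 and 10 members above 0. With the dye-flip arrays negated the list lay within the random range (0.08 and -0.07, percentiles 44.8 and 21.7 among lists matched on signal). HES1, the best known target, read 0.46 at 12 h (arrays 0.93 and -0.01) and 0.44 at 24 h (0.27 and 0.62) and was not called. DTX1 and HES1 had dim probes, at signal percentiles 19.4 and 18.7. ID1 read 0.45 at 24 h, and MYC, also on this list, -0.42 and -0.13. The 12 h percentile was 95.6 against unmatched random lists. The Notch receptors, ligands and pathway machinery had 0 calls among 18 and 19 measured genes, with medians of 0.06 and 0.03. Their largest values were those of RBPJ, the DNA-binding partner of NICD (-0.30), and DLL3 (0.26) at 12 h, and those of DLL4 (0.41) and ADAM17 (0.37) at 24 h.

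Among 21 measured goblet cell and mucin genes, TFF1 was called higher at both times, GCNT3 lower at 12 h, and AGR2 and SPINK1 lower at 24 h. The remaining 19 and 18 were not called. AGR2 also read -0.90 at 12 h and GCNT3 -0.58 at 24 h, neither called, whereas SPINK1 read 0.32 at 12 h. The list medians of 0.07 and 0.02 lay within the random range. This depends on the direction at 12 h. With the dye-flip arrays negated the medians were -0.06 and -0.07, at percentiles 0.33 and 13.75 among lists matched on signal. The secretory lineage transcription factors had 0 calls among 10 genes (medians 0.03 and -0.07). In that list SOX4 read 0.24 (arrays 0.58 and -0.11) and 0.34, and NEUROG3 -0.18 (0.05 and -0.41) and -0.31. The enteroendocrine genes had 0 calls among 19 (0.08 and 0.08), with SCGN at 0.86 and CHGA at 0.58 at 12 h, and SST at 0.45 and SCG2 at -0.36 (arrays -0.86 and 0.15) at 24 h. The 28 absorptive enterocyte genes had 0 calls at either time (0.08 and 0.09), although CDX1 averaged 1.17 (arrays 2.34 and -0.01) and MTTP 0.82 (2.13 and -0.48) at 12 h and CEACAM7 1.55 and FABP2 0.85 at 24 h; only FABP2 had arrays close together (0.82 and 0.87). Of the intestinal stem cell and Wnt target genes, 0 of 21 at 12 h and 0 of 20 at 24 h were called (0.04 and -0.04). ID2, which is on this list and on that of TGF-beta and BMP targets, came close, at -0.93 ± 0.12 and -1.0 ± 0.11. LGR5, the crypt stem cell marker, read 0.22 and 0.11, TNFRSF19 1.46 at 12 h (arrays 3.08 and -0.16), and ASCL2 -0.86 at 24 h.

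The genes of cell proliferation and mitosis had low medians at both times, at -0.12 at 12 h and -0.19 at 24 h, below 10000 of 10000 random lists in each case (percentile 0.0). This depends on the reading of the direction. With the dye-flip arrays negated the medians were -0.02 and -0.01, at percentiles 23.5 and 24.1 among lists matched on signal. The arrays are not centred, and relative to the median of all genes the list lay at -0.35 on the Cy5 array and -0.01 on the dye flip at 12 h, and at -0.26 and -0.33 at 24 h. None of the 23 members was called, so no single gene is said to have fallen. At 12 h 15 members were below 0, and at 24 h 21 were. AURKA, a mitotic kinase, read -0.63 ± 0.02 at 24 h and UBE2C, a ubiquitin-conjugating enzyme of mitotic exit, -0.60 ± 0.04. The largest 12 h values were those of CENPE (-0.78, arrays -1.66 and 0.11) and PRC1 (0.43). The list's median of 24 h minus 12 h was -0.12 (percentile 0.81), but relative to all genes the orientations read 0.08 and -0.31. The DNA replication genes had 0 calls among 24 and medians of 0.09 at 12 h (percentile 95, and 98.4 among lists matched on signal) and -0.09 at 24 h (percentile 0.55), with a median of 24 h minus 12 h of -0.17 (percentile 0.24) and 21 members lower at 24 h than at 12 h. Relative to all genes the orientations of that difference read 0.03 and -0.27. In that list POLD1 read 1.09 and UHRF1 0.56 at 12 h, both with arrays of opposite sign or very unequal size, and CDC45 read -0.48 and E2F2 -0.74 (arrays -1.70 and 0.21) at 24 h. The cell cycle inhibitors and p53 targets had medians of 0.06 and 0.13, with 0 calls at 12 h and 1 at 24 h (CDKN2B). CDKN1A read 0.08 and 0.28, and at 12 h CDKN2B averaged 1.82 (arrays 3.50 and 0.13) and CDKN2D -1.59 (arrays -2.89 and -0.29), neither called.

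**Figure D3:**
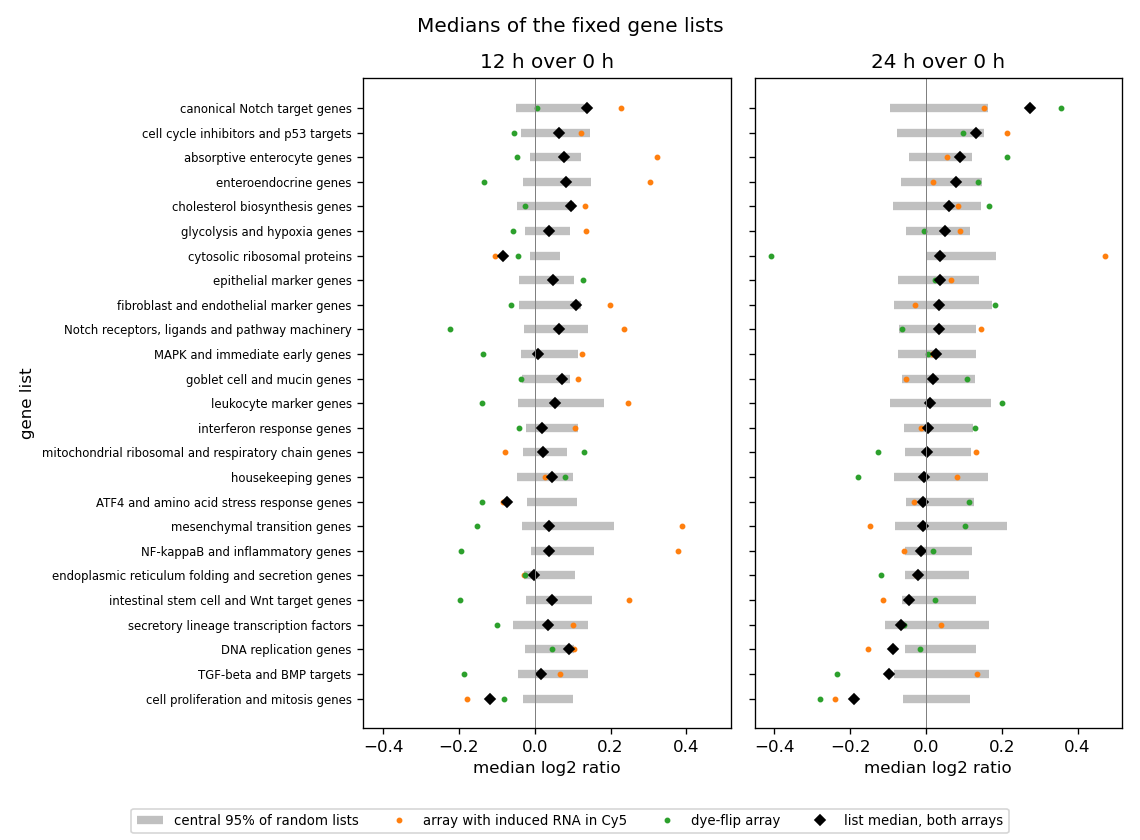
Median log2 ratio of each of the 25 gene lists at 12 h and 24 h over 0 h (diamonds), with the medians on each array (dots) and the central 95% of 10000 matched random lists (grey bars). The mitosis genes lie left of the bar at both times (-0.12 and -0.19) and the canonical Notch targets right of it (0.14 and 0.27).

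Several stress and metabolic lists were measured as well. The ATF4 and amino acid stress response genes had a median of -0.07 at 12 h (percentile 0.01), with GDF15 lower among 27 members, and -0.01 at 24 h (percentile 15.7), when GDF15 read -0.98 and SLC7A1 0.75. The cytosolic ribosomal proteins had a median of -0.08 at 12 h (percentile 0.0, 45 of 55 below 0), at -0.28 and 0.03 on the arrays relative to all genes, and at percentile 100 among lists matched on signal with the dye-flip arrays negated (-0.01). Among them were RPL9 at -0.29 and RPL31 at -0.25. At 24 h their median was 0.04, with 0.47 on the Cy5 array and -0.41 on the dye flip, so the arrays as deposited opposed each other. The percentile was 11.1, and 99.0 among lists matched on signal, so it depended on the matching. RPS21 read 0.31 and RPS23 0.27. With the dye-flip arrays negated the 24 h arrays of this list went together instead. Its median was then 0.46, at percentile 100 among lists matched on signal. The glycolysis and hypoxia genes had 1 call at each time, SLC2A1, and medians of 0.04 and 0.05. The cholesterol biosynthesis genes had 0 calls among 15 (0.10 and 0.06), with MSMO1 at 0.25 and DHCR7 at 0.24 at 12 h and ACAT2 and FDPS both at 0.35 at 24 h. The genes of endoplasmic reticulum folding and secretion had 0 calls among 25 and 12 and 10 members above 0, with P4HB at 0.31 and DNAJC3 at 0.42 (arrays 1.07 and -0.23) at 12 h and MANF at -0.46 and DNAJB11 at -0.40 at 24 h. The mitochondrial ribosomal and respiratory chain genes had 0 calls among 24, with 16 and 12 members above 0; ATP5F1C read 0.22 and NDUFV1 0.12 at 12 h, and MRPS12 -0.43 and MRPS7 -0.23 (arrays 0.02 and -0.47) at 24 h.

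The signalling and identity lists held few or no calls. The TGF-beta and BMP targets had 0 calls among 15 and medians of 0.02 and -0.10, the latter at percentile 1.53 but with the arrays apart (0.13 and -0.23). Here SKIL averaged 1.19 at 12 h (arrays 2.57 and -0.19) and BMP4 -0.61 at 24 h. The MAPK and immediate early genes had 0 calls among 17 and 10 and 9 members above 0, with EGR3 at 0.43 and 0.31, JUN at -0.44 at 12 h and DUSP4 at -0.33 at 24 h. The interferon response genes had 0 calls among 25, with 15 members above 0 at each time; IFI27 averaged -0.73 (arrays -1.75 and 0.29) and OAS2 -0.49 (0.41 and -1.39) at 12 h, and IFI44L -0.98 (-2.52 and 0.57) and RIGI 0.51 (0.13 and 0.90) at 24 h. The NF-kappaB and inflammatory genes had 0 calls among 24 and medians of 0.04 and -0.01, with CXCL8 at 1.36 (arrays 3.39 and -0.67) and CXCL5 at 0.81 at 12 h, and LCN2 at -0.89 and TRAF1 at -0.53 at 24 h. The epithelial markers had 0 calls among 16 (0.05 and 0.04); DSP read 0.47 ± 0.05 and 0.57 ± 0.01, CLDN1 -0.69 at 12 h (arrays -1.50 and 0.12) and KRT18 -0.86 at 24 h. The mesenchymal transition genes had 0 calls among 15 and 8 and 7 members above 0, with ITGA5 at 1.27 (arrays 2.58 and -0.04) and MMP9 at -0.64 (-1.71 and 0.42) at 12 h and TGFB1 at -1.08 (-2.36 and 0.20) and TGFB2 at 0.54 (0.12 and 0.97) at 24 h. The housekeeping genes had 0 calls among 14 and 9 and 7 members above 0, with TFRC at -0.48 and EEF1A1 at 0.32 at 12 h and TFRC at 0.47 and ACTB at -0.36 at 24 h. Markers of cell types that a cell line should not hold were not called either: 0 of 14 fibroblast and endothelial genes (LUM 0.58, arrays 2.60 and -1.44, and CDH5 0.33 at 12 h, FAP 0.67 and THY1 0.49, arrays -0.01 and 0.99, at 24 h) and 0 of 13 and 12 leukocyte genes (FCGR3A 0.86, arrays 1.96 and -0.24, and LCP1 0.79, arrays 2.02 and -0.43, at 12 h, SPI1 0.53 and CSF1R 0.43 at 24 h). KLF4, a transcription factor of goblet cell differentiation, read -0.05 and 0.05.

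Of the 25 lists, 3 lay below and 1 above the central 95% of random lists at 12 h, 3 and 1 at 24 h, and 3 and 4 for 24 h minus 12 h. The 4 above the range for the difference were the cytosolic ribosomal proteins (0.13, with the orientations at 0.63 and -0.36), the ATF4 and amino acid stress response genes (0.12), the canonical Notch targets (0.13, with the orientations at -0.10 and 0.16 and a mean of -0.01) and the glycolysis and hypoxia genes (0.08, percentile 97.0 against unmatched lists). The 3 below it were the mitosis genes, the DNA replication genes and the NF-kappaB and inflammatory genes (-0.15, with the orientations at -0.40 and 0.11). With the dye-flip arrays negated and random lists matched on signal, only the ribosomal list stayed outside the range where it had been outside. It lay above it at 12 h instead of below, above it for the difference, and also above it at 24 h (percentile 100). Further positions outside the range appeared only with these arrays negated. At 12 h they were those of the goblet cell (percentile 0.33), endoplasmic reticulum (1.61), NF-kappaB (98.2) and mesenchymal lists (99.5). At 24 h they were those of the Notch machinery (97.8) and mesenchymal lists (0.83), and for the difference the p53 (99.0) and mesenchymal lists (2.34). The DNA replication genes then lay at percentile 42.8 at 24 h and 84.2 for the difference, the ATF4 genes at 16.4 at 12 h and the TGF-beta and BMP targets at 96.1 at 24 h. Lists overlap in members, and the percentiles describe these arrays and are not tests of the conditions.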

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

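For 11 of 115 named genes and 1 of 25 list medians, both arrays at 12 h lay on one side of 0 and both arrays at 24 h on the other. The difference between the time points was not tested, since each has 1 replicate. Random signs on 4 arrays would give such a pattern for 12.5% of genes. That is not a chance rate for this set, because many named genes were picked by their values and the arrays are not centred.

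The values at 24 h minus those at 12 h were as follows. SPINK1 is not among them, because its 12 h arrays had opposite signs. GPR22 was lower at 12 h (arrays -1.41 and -1.12) and near 0 at 24 h (0.02 and 0.33), a difference of 1.44. TFRC, the transferrin receptor, read -0.27 and -0.69 at 12 h and 0.27 and 0.67 at 24 h, a difference of 0.96. CXCL5 went from 1.21 and 0.41 to -0.35 and -0.09 (-1.04), CHGA from 0.63 and 0.52 to -0.55 and -0.03 (-0.86), and PRC1 from 0.73 and 0.13 to -0.27 and -0.31 (-0.72). P4HB went from 0.26 and 0.36 to -0.03 and -0.39 (-0.52), and ACTB from 0.24 and 0.03 to -0.34 and -0.39 (-0.49). SPI1 went from -0.62 and -0.15 to 0.39 and 0.66 (0.92). RALGPS1 (2.65) and LINC00652 (3.24) rest on a single extreme array each, at -4.11 for RALGPS1 at 12 h and 5.61 for LINC00652 at 24 h. KLF4 differed by 0.11, with all 4 arrays within 0.10 of 0. The DNA replication list had medians of 0.10 and 0.04 on the 12 h arrays and -0.15 and -0.02 on the 24 h arrays, and a median difference of -0.17. Relative to the median of all genes on each array these were -0.07, 0.12, -0.17 and -0.07, so the signs at 12 h opposed each other.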

How the results depend on the processing

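Leaving out the dimmest 50%, the lowess correction, negating the dye-flip arrays and the count of probes with a gene symbol were chosen after the data were seen. The 10 genes higher at both times (38 and 57 per time point, 32 for the difference; lower 5, 7 and 19, and 1 at both) depended least on the processing. All 11 genes called at both times remained after centring and after lowess, and 10 of them after quantile normalization and with each array at 2-fold (without SERPINI1). Leaving out the dimmest 50% removed SGK1 and kept the other 10. It cannot change the values of the genes kept, so it is no check of those 10.

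Demanding 2-fold on each array gave 18 higher and 2 lower genes at 12 h, 31 and 3 at 24 h, 14 and 6 for the difference, and 0 lower at both. With no demand on single arrays the counts were 106 and 38, 102 and 32, and 89 and 125. A mean of 1.5-fold gave 212 and 52, 279 and 79, 194 and 184, and 44 and 10 at both. These follow from the stricter or looser rule. Without the dimmest 50%, 14 and 3 genes were called at 12 h, 15 higher at 24 h, and 0 and 2 for the difference, with fewer genes entered, and r was 0.463. Among these brighter genes, 12 h and 24 h arrays of the same dye orientation correlated at 0.358 and 0.41. Those of opposite orientation correlated at 0.127 and -0.029, so this r depended on dye orientation too. Centring gave 2 lower at both. Quantile normalization gave 3 lower at 12 h and 32 lower for the difference. Counted per probe, 9, 23 and 31 were lower, against 5, 10 and 20 over probes with a gene symbol, so most of this move came from probes without one. Lowess gave 4 lower at 24 h. Without the 10% with the largest dye part, r was 0.360. Across dye orientations r was 0.134 and, reversed, -0.111. For centring, quantile normalization, lowess and r the cause was not tested.

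Leaving out 1 array, which leaves dye bias unbalanced, gave 39 to 567 higher and 70 to 109 lower genes at 12 h. At 24 h it gave 104 to 312 and 35 to 120. For the difference a whole dye orientation was left out, 1 array of each time point, which gave 128 to 485 higher and 24 to 729 lower genes. A dye bias common to both time points cancels within an orientation. Leaving out 1 array gave 10 to 28 genes higher and 0 to 2 lower at both times, and r ranged from 0.067 to 0.247. Of the list medians under alternatives, 41 moved by more than the spread between the arrays and 334 did not. Of the list percentiles, 28 crossed an end of the central 95%, most of them with the dye-flip arrays negated, and 197 did not, and of the named gene values 14 moved and 546 did not. Leaving out 1 array shifts a gene's mean by its technical error, which cannot exceed that spread. Choosing the probe with the smallest dye part cannot move a gene with 1 probe. A list median without 1 array is that of the other array, which helps to set the spread. The unmoved gene values and list medians are therefore no measure of robustness. Signal over background is not given.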

Other observations

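The genes and tests in this part were chosen after their values were seen, except for the gene lists and the overlap of calls. Among the brighter genes, several others were called with arrays close together. GMNN, which encodes the replication licensing inhibitor geminin, read 1.60 and 1.77 at 12 h and 0.89 and 0.81 at 24 h, and was called at 12 h only. TDO2, the tryptophan-degrading dioxygenase, read 0.81 and 0.79 at 12 h and 1.86 and 1.74 at 24 h, and was called at 24 h only. IL18, an epithelial cytokine, read 0.98 and 1.03 at 24 h, and OTC, a urea cycle enzyme, 1.15 and 1.05. SLC28A2, a nucleoside transporter, averaged 1.79 at 24 h with an error of 0.35. At 12 h the keratin gene KRT13 averaged 1.10 and the kallikrein gene KLK10 1.08. Whether any of these differ between the times was not tested. Probes with no gene symbol also passed the rule at both times: AGhsA141122 averaged 1.25 and 1.37, and AGhsA270207 2.39 and 1.65.

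The dye part met the calling rule for 106 genes at 12 h and 66 at 24 h, at least as many as were called. Dim probes may account for most of this. With signal taken from the dye-flip array of the other time point, 124 of 170 such genes (72.9%) lay in the dimmest 25%, where 25% would lie by chance. Called genes in the dimmest 25% by both dye-flip arrays are open to the same error. Among genes measured on all 4 arrays these were 17 higher and 1 lower at 12 h, and 34 and 0 at 24 h. PBOV1, called lower at 24 h at signal percentile 2.06, was not measured on all 4 arrays and is not in these counts. No biological explanation was tested for this pattern.

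For the 11 genes called in the same direction at both times, the tables argue against errors independent at each time and equally likely for every gene. Lists of these lengths would then share 0.24 higher genes, and the dye part shared 2. Dye-part calls fell mostly on dim genes, however, and no expected number was computed for genes of unequal error. Probe-specific dye bias would also repeat over all 4 arrays had the dye-flip arrays been deposited unturned; bright probes of a gene went together at r = 0.389 as deposited (114 genes; r = 0.105 over all 369), but its interval overlaps that with the dye-flip arrays negated, so this cannot be told apart. A deviation of the 0 h RNA stays open as well. Unchanged cultures with a common control, with all spread taken as culture spread, gave 42.7 genes past 2-fold on average at both times, 14.5 higher and 28.2 lower. With no demand on single arrays 15 higher and 1 lower were observed, so this simulation meets the higher side and not the lower side, and as a model with assumed spread it excludes nothing. The induction of NICD1, doxycycline itself and time in culture are further candidates that the design does not separate, and were not tested.

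The median of the mitosis genes was low at both times. The DNA replication genes did not go with it at 12 h (median 0.09, percentile 95, or 98.4 among lists matched on signal, 15 of 24 above 0) and were low at 24 h (-0.09, percentile 0.55, but 42.8 with the dye-flip arrays negated). A trend of the ratios with signal was argued against: among random lists matched on recovered signal the median lay at percentile 0.01 or below at both times. The direction of the dye-flip arrays stays open: with these negated the median at 24 h was -0.01, so dye bias of the probes cannot be told apart had the arrays been deposited unturned. The difference of 24 h and 12 h, in which a 0 h extract used for both times would cancel, does not decide about that extract. It lay at percentile 0.81 (2.5 with unmatched lists), but relative to all genes the dye orientations read 0.08 and -0.31, so only the dye flip carried the fall. The labels also do not say that 1 extract was used. For the value at 12 h (-0.12; relative to all genes -0.35 on the Cy5 array and -0.01 on the dye flip) a deviation of the 0 h RNA cannot be told apart from a change in the cells, because there is 1 control. Fewer dividing cells after induction and growth of the culture over time could lower these genes as well. Neither was tested, and deciding between them would take counts of dividing cells in cultures with and without induction at the same time.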
